A study of Eohaustorius estuarius with 14 samples.

How the data were processed

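Total RNA of whole amphipods was labelled with Cy3 and hybridised to a single-colour Agilent custom array, per the labels' protocols. The 14 scanner files hold the linear intensity of each spot as the authors deposited it, and per the file headers Agilent Feature Extraction 10.1.1.1 had subtracted background and removed spatial and multiplicative trends within each array, with surrogate values for low signals. The submitters' processing notes name version 9.1 of the same program. The processed signal intensity, the raw mean spot intensity, the local background and the 0 or 1 quality flags were used as deposited. The authors also deposited a table of log2 values per probe. Set against the scanner values, its columns matched quantile-normalised log2 processed signal centred on each probe's median over the 14 arrays, with a median absolute difference between 0.000554 and 0.000909 and column medians from -0.09 to 0.07, which settled its scale, centring and direction. It served as an alternative.

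Groups came from the labels (6 control and 8 cyfluthrin arrays). Samples are numbered as in the labels' descriptions, where a and b after control 3 and cyfluthrin 8 were taken as repeat arrays of the same sample. Their arrays were averaged and counted as 1 sample, leaving 5 and 7. All processing choices, the design, the gene lists and the rule for named genes were fixed before the data were examined. Each array held 15208 spots of 8507 probes. Spots flagged as outliers were left out unless all spots of a probe were flagged, spots of a probe were averaged on the log2 scale, and the log2 of each array's 75th percentile was subtracted. No processed signal was below 1, the floor set for the log. A probe was tested where it was well above background in at least 0.5 of the samples of a group, which kept 7721 probes and left out 786. Only 1 probe was saturated on any array, and none of the called ones was. The number of arrays limits the precision.

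Tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term) with Benjamini-Hochberg adjustment at 0.05. Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3 read the files, and matplotlib 3.10.9 drew the plots. The 16 gene lists were built by patterns on the descriptions and tested with camera (preset correlation 0.01, and estimated correlation) and fry, adjusted over the lists. Probes of the same name were tested separately. The named genes are the 10 largest rises and 10 largest falls among called probes with a name (none described as uncharacterized, hypothetical or unknown), with 1 probe per name, filled up to 10 with the lowest p in that direction where fewer were called, plus the 2 lowest p of each list. Spread and array quality were compared by exact permutation over the 792 splits of the samples. Slide and row were read from the headers. Gene names are those of the array design, and 4967 probes have no description there.

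The test was checked on simulated data for this comparison, with 200 of 7721 probes changed in each of 10 runs. It recovered 18.8% of changes of 1.5-fold, 57.6% of 2-fold, 88.2% of 4-fold and 96.4% of 8-fold, with 6.5 false calls a run and 0.1 calls where nothing was changed. The simulated noise was independent between probes and samples, unlike the real arrays. These false calls therefore do not cover calls that arise from structure shared between samples.

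The alternatives were normexp background correction (offset 50), quantile, cyclic loess and median scaling, other filters on dim probes, other treatment of the repeat arrays, sample and title numbers as blocks, slide as a random and as a fixed block, row as a covariate, array weights, the deposited log2 table, trended and robust eBayes, a fold threshold of 1.5, and leaving out each sample in turn. Fits to row 2 arrays, without cyfluthrin 1 and 2, with a cuticle component as a covariate, with cyfluthrin 4 and 8 averaged, and gene list tests without the probes at least 4-fold higher, with slide as a block or with row as a covariate were added after seeing the data.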

Results

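Transcript levels were measured in whole bodies of *Eohaustorius estuarius*, an estuarine burrowing amphipod used in sediment toxicity tests, after 10 days on sediment spiked with cyfluthrin at a nominal 1.6 µg/kg or with solvent alone. Cyfluthrin is a pyrethroid insecticide, a class that keeps voltage-gated sodium channels of nerve cells open. The arrays came from a single laboratory of an interlaboratory comparison and asked which transcripts differed between exposed and control animals and how repeatable the array values were. The set held 6 control and 8 cyfluthrin arrays. Control sample 3 and cyfluthrin sample 8 were each represented by a pair of arrays, which were averaged, so that 5 control samples (1 to 5) and 7 cyfluthrin samples (1 to 6 and 8) were compared. The custom array carried 8507 probes of 60 bases, each designed to a contig of a transcript assembly of the species, and 3540 of them had a description in the array files. Items are given by that description and contig number, without genome coordinates, since no genome was used here. Between 74.3% (control 5) and 93.3% (cyfluthrin 3) of the probes lay well above background on an array, and 7721 probes were tested. The number of arrays limits the precision, and the median standard error of a log2 fold change was 0.21. The labels do not say whether the samples came from separate exposure vessels, so p-values measure the spread between these samples.

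Cyfluthrin-exposed amphipods differed from controls in 47 probes, of which 30 were higher and 17 lower. A 60S ribosomal protein (contig 6676) was 11.4-fold higher (log2 fold change 3.52 ± 0.46, SE, n = 5 and 7, limma adjusted p = 0.00651). It was well above background on 3 of the 6 control arrays, and with normexp background correction it was at 1.44 and not called. Heat shock protein 90 (contig 5659), a chaperone of signalling proteins, was 9.06-fold higher (3.18 ± 0.44, limma adjusted p = 0.00852). A stress-seventy subfamily A protein (contig 4071), named for the 70 kDa chaperone family, was 7.99-fold higher, and the p23 co-chaperone (contig 5795), a partner of heat shock protein 90, was 7.20-fold higher. The largest fall was in heat shock protein 70 (contig 2087), at a log2 fold change of -2.65 ± 0.37 (limma adjusted p = 0.00852). In these 5 named probes every cyfluthrin sample lay beyond every control sample.

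**Figure D1:**
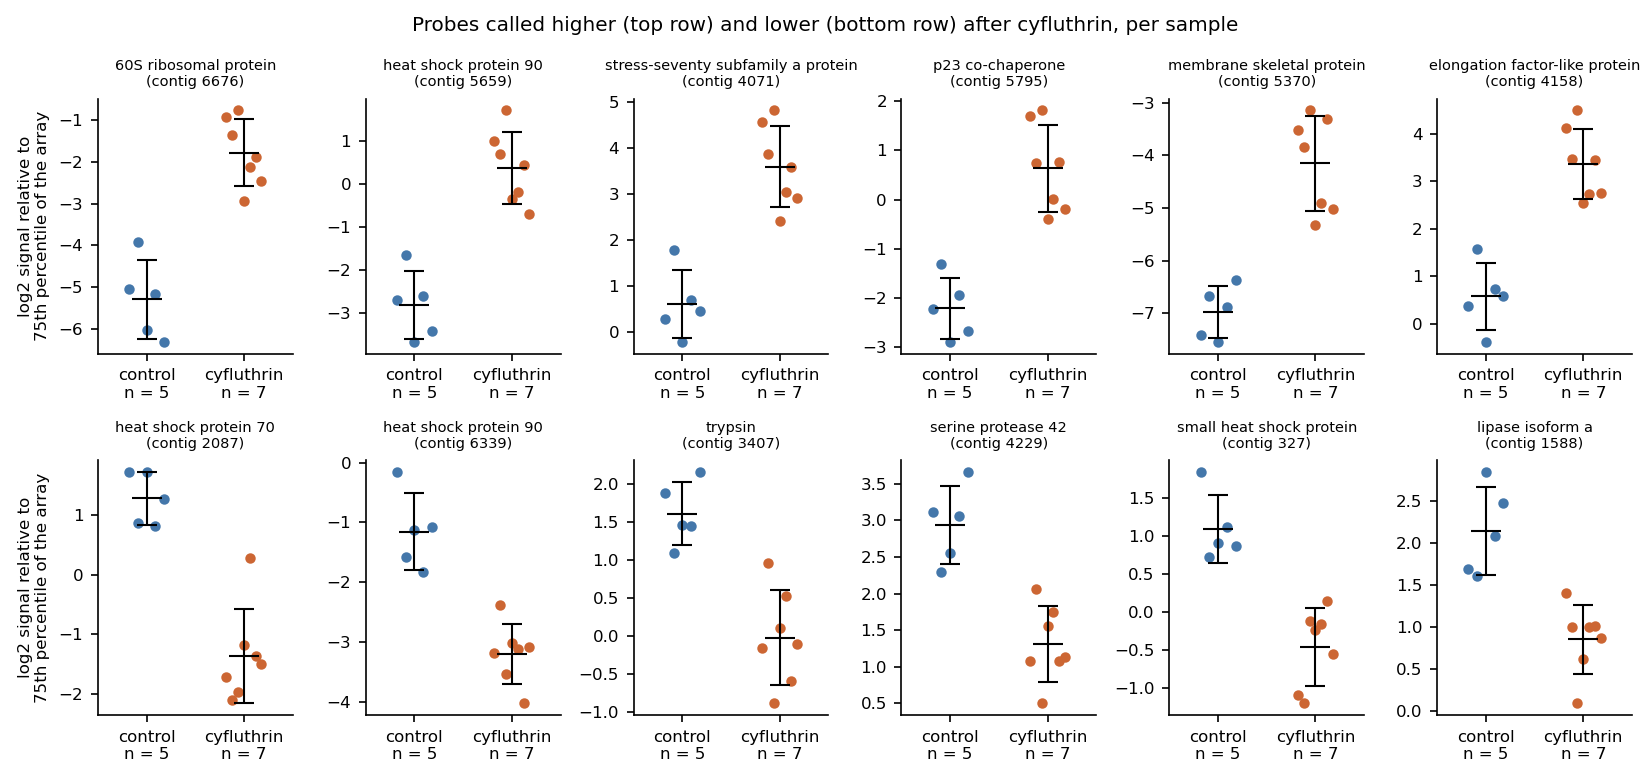
Normalised log2 signal of 12 called probes in each sample (vertical axis, relative to the 75th percentile of the array), for 5 control and 7 cyfluthrin samples, with mean and SD as bars. The 12 were chosen among called named probes whose groups do not overlap. Heat shock protein 70 (contig 2087) in cyfluthrin 5 lies highest of its group at 0.28.

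Further rises complete the 10 largest with 1 probe per name, hypothetical proteins left out. The hypothetical protein of contig 6094, described from a plant (*Vitis vinifera*) and chosen after its values were seen, rose 7.08-fold. Actin (contig 4390), the main protein of thin filaments, rose 6.84-fold, a translation elongation factor-like protein (contig 4158) rose 6.89-fold, and heat shock protein 83-1 (contig 4735) rose 6.55-fold. Only 1 of 5 tested probes named actin was called, and 1 of 2 with the elongation factor-like name. A probe described as myeloid leukemia (contig 7113) rose 6.89-fold (log2 fold change 2.78 ± 0.56, limma adjusted p = 0.0483). Its groups overlapped, and it lost its call in 9 of the 12 fits that left out 1 sample (controls 1, 3, 4 and 5, cyfluthrin 1, 2, 3, 5 and 6, limma adjusted p up to 0.163) and with normexp (log2 fold change 2.36). An alkyl hydroperoxide reductase (contig 7422), an enzyme that reduces peroxides, rose 6.20-fold. This call was lost in 7 such fits (controls 1, 3, 4 and 5, cyfluthrin 1, 2 and 6, limma adjusted p up to 0.112) and with normexp (log2 fold change 2.03). A membrane skeletal protein (contig 5370) had a log2 fold change of 2.82 ± 0.41 (limma adjusted p = 0.00935), only 1 of its 6 control arrays was well above background, and with normexp it was at 0.64 and not called. The lowest p of all belonged to a nattectin precursor (contig 1240), a C-type lectin first described in fish venom, which was chosen after its values were seen. It rose 3.58-fold (1.84 ± 0.16, limma adjusted p = 0.000577). Of the called probes, 16 were at least 4-fold higher by the fitted fold change and 3 at least 4-fold lower, 15 of the 47 had no usable name, and fold changes ran from 1.64 to 11.4. For 4 called probes no array of the control group was well above background, among them 14-3-3 (contig 3155), among the 16 and given here as at least 3.56-fold higher, and an rnp-1 like RNA-binding protein (contig 5683), at least 2.38-fold higher, both chosen after their values were seen. The bound sets the mean of the cyfluthrin samples against the lowest signal well above background on the control arrays, or the probe's own signal where that was higher.

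Groups did not overlap in 41 of the 47 called probes and in 83 of all 7721 tested (1.07%, against 0.253% by chance), and 694 probes had an unadjusted p under 0.05 where 386 are given by chance. The arrays lay on 4 slides that each held both groups, and the median log2 fold change of the 16 probes at least 4-fold higher was 2.57, 2.57, 3.40 and 3.02 within slides 1 to 4. With slide as a fixed block limma called 35 probes. All control arrays lay in row 2 of the slides against only 2 of the 7 cyfluthrin samples. Row 1 held no control, so a fit with row as a covariate took its fold changes from cyfluthrin 4 and 8 against the controls. In that fit the median of the 16 was 1.86 against 2.78, and 3 probes were called. There were 19 with normexp background correction, and 21, 24, 21 and 31 without control 1, control 3, control 5 and cyfluthrin 6.

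The called heat shock and chaperone probes moved in opposite directions. Of 73 tested probes of this list, 10 changed, 5 up and 5 down, and 14 (8 up, 6 down) passed when adjusted over the list alone. The name pattern of this list did not take the stress-seventy subfamily A protein above, which rose. Besides the probes named above, a second heat shock protein 90 probe (contig 4879) rose 7.33-fold and a heat shock protein 70 probe (contig 52) rose by a fitted 3.09-fold, with only 1 of its 6 control arrays well above background. Of the 5 rises 4 were among the 16 probes at least 4-fold higher, which varied together and whose source stays open (see the closing section). The falls were in heat shock protein 70 (contigs 2087, 2561 and 2088, at log2 fold changes of -2.65, -2.46 and -1.83), in heat shock protein 90 (contig 6339, -2.04 ± 0.31, limma adjusted p = 0.0101) and in a small heat shock protein (contig 327, -1.55 ± 0.27, limma adjusted p = 0.0207). Probes of the heat shock protein 90 name thus differed in direction between contigs. Called were 3 of 8 tested probes of that name and 4 of 7 of the heat shock protein 70 name. The fry test found changes in either direction in the list (adjusted p = 1.92e-05) and no shift one way (adjusted p = 0.587), and camera found none (adjusted p = 0.749, 0.879 with an estimated correlation), with a list mean of 0.11 and median of 0.00. Within slides 1 to 4 the median of the 5 fallen probes was -2.07, -1.52, -2.03 and -2.64. With normexp the fall of contig 6339 was not called (log2 fold change -1.15). The small heat shock protein lost its call without control 1, 3, 4 or 5 (log2 fold change -1.37, -1.60, -1.55 and -1.61).

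Of 59 tested digestive enzyme probes 2 fell. Trypsin (contig 3407), a gut protease, had a log2 fold change of -1.63 ± 0.30 (limma adjusted p = 0.032), and lipase isoform a (contig 1588), a fat-splitting enzyme, -1.28 ± 0.26 (limma adjusted p = 0.0483). Adjusted over the list alone 5 probes passed, 4 lower and 1 higher, and they included phospholipase D-gamma (contig 5886), a membrane lipid enzyme that the name pattern also took, cathepsin D (contig 2525), a lysosomal and gut protease, and X-Pro aminopeptidase (contig 4495), which was the higher value. Cathepsin D and the aminopeptidase were chosen after their values were seen. So was chymotrypsin 1 (contig 2468), the largest rise of the list at 1.20, which was not called (limma adjusted p = 0.287). The name pattern also took methionine aminopeptidases and a lysosomal alpha-mannosidase, so not every probe of the list is a gut enzyme. The list mean was -0.18, with 40 probes below 0 and 19 above. Camera called the list lower (adjusted p = 0.0244) at the preset correlation. With the estimated correlation of 0.173 the camera adjusted p = 0.732 was not past the threshold. Fry found changes in either direction (adjusted p = 0.0243) and no shift one way (adjusted p = 0.513). The list's mean within slides 1 to 4 was 0.03, -0.38, -0.03 and -0.28, and with slide as a block the camera adjusted p was 0.135. The preset call was lost without control 4, control 5, cyfluthrin 3 or cyfluthrin 6 (camera adjusted p = 0.0645, 0.104, 0.137 and 0.0579), and on row 2 arrays alone (mean -0.18), over a range of 0.00228 to 0.732 in all alternatives. Of the single probes, trypsin lost its call in 8 of the 12 fits without 1 sample (controls 1, 3, 4 and 5, cyfluthrin 1, 4, 6 and 8, limma adjusted p up to 0.118). Lipase lost it in 10 (all but control 2 and cyfluthrin 1, up to 0.164), as well as with normexp (log2 fold change -1.25) and quantile normalisation (-1.26). Serine protease 42 (contig 4229), outside the list, fell by 1.63 on the log2 scale (limma adjusted p = 0.0228), and lost its call in 7 of these fits (controls 1, 3, 4 and 5, cyfluthrin 1, 6 and 8, up to 0.0872).

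**Figure D2:**
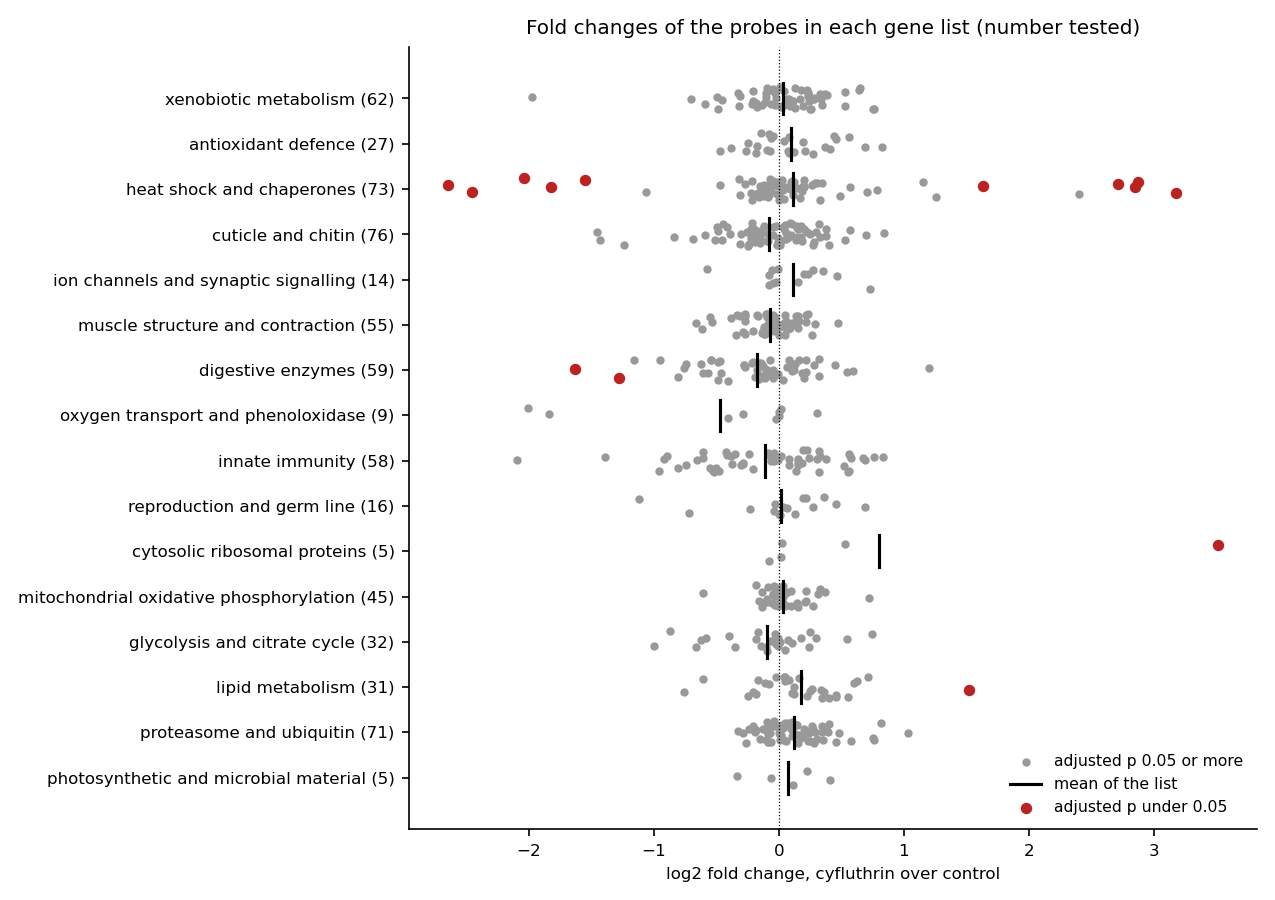
Log2 fold change of each tested probe (horizontal axis, cyfluthrin over control) in the 16 gene lists, with the number tested in brackets, red points for probes with a limma adjusted p under 0.05 over all probes tested and a bar at the list mean. The heat shock list holds 5 red points on each side, and the digestive enzyme list has a mean of -0.18.

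Phosphoenolpyruvate carboxykinase (contig 1428, 1 of 2 tested probes of the name called), the entry enzyme of gluconeogenesis, fell by 1.01 on the log2 scale (limma adjusted p = 0.0166). Its call was lost with normexp (log2 fold change -0.63, limma adjusted p = 0.999) and without control 1 or control 5 (limma adjusted p = 0.0684 and 0.0567). Sphingomyelin phosphodiesterase (contig 3482, 1 of 5 tested probes of the name called), which splits a membrane sphingolipid, fell by 1.22 (limma adjusted p = 0.013). That call was lost with normexp (-0.91, limma adjusted p = 0.24) and without control 5 (limma adjusted p = 0.0523). The remaining named values in this direction did not pass, with laccase 1 (contig 2001), a multicopper oxidase, at -1.11 (limma adjusted p = 0.0544, 0.0089 without control 2) and histone H1 (contig 5112) at -0.73 (limma adjusted p = 0.0588, 0.0387 without control 4 and 0.0386 without cyfluthrin 5). In the lipid metabolism list 1 of 31 tested probes changed, the very low-density lipoprotein receptor (contig 3297), which rose 2.87-fold (limma adjusted p = 0.0483), and 2 passed when adjusted over the list alone. The receptor lost its call in 10 of the 12 fits without 1 sample (all but control 4 and cyfluthrin 3, limma adjusted p up to 0.168). With normexp it was at 1.01 on the log2 scale and not called. In the list of cytosolic ribosomal proteins 1 of 5 rose, the 60S ribosomal protein above, so that the list mean of 0.80 lay far above its median of 0.02. Camera called neither list (adjusted p = 0.154 for each), and fry found changes in either direction in both (adjusted p = 0.0492 and 0.0458).

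Lists on ion channels and synapses, xenobiotic metabolism and antioxidant defence held no called probe, and no tested probe was described as a sodium channel. None of 14 ion channel and synaptic probes passed over all probes (1 did when adjusted over the list alone), with the ligand-gated chloride channel homolog 3 (contig 7585) at 0.73 ± 0.15 (limma adjusted p = 0.0627) and an acetylcholinesterase precursor (contig 1513) at -0.58 (limma adjusted p = 0.345). None of 62 xenobiotic metabolism probes passed, and their lowest p values belonged to cytochrome P450 probes (contig 2661 at -0.70, contig 2965 at -0.49). Antioxidant defence (27 tested) held none, with thioredoxin domain containing 17 (contig 4954) at 0.83 and thioredoxin-like protein 4a (contig 7234) at 0.41. Its name pattern did not take the alkyl hydroperoxide reductase above, which rose. By unadjusted p under 0.05 the same test listed 694 probes in all, and camera called no list among these (adjusted p = 0.412, 0.736 and 0.736 respectively). Fry found changes in either direction in the ion channel list (adjusted p = 0.0465), not in the other two (adjusted p = 0.361 and 0.560), and no shift one way in any of them.

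The other lists had no called probe either. Proteasome and ubiquitin probes (71 tested) had 1 that passed when adjusted over the list alone, 26S proteasome non-ATPase subunit 2 (contig 1721, described as macropain), at 0.82 ± 0.17 (limma adjusted p = 0.0618, 0.0353 without control 4), with subunit 6 (contig 2839) at 0.76 (limma adjusted p = 0.183, 0.036 without cyfluthrin 4). Innate immunity (58 tested) had a c-type lectin (contig 1221) at -0.92 and a toll-like receptor (contig 5123) at -0.61. Its name pattern did not take the nattectin precursor above, which rose. Oxygen transport (9 tested) had haemocyanin contig 356 at -2.01 ± 0.77 (limma adjusted p = 0.427) and hemocyanin subunit 1 (contig 807) at -1.84 ± 0.75 (limma adjusted p = 0.475). Without control 2, where both were low, they were at -2.72 and -2.54 and still not called. Glycolysis and citrate cycle (32 tested) had hexokinase A (contig 5320) at -1.0 and pyruvate dehydrogenase (contig 3560) at -0.62. The name pattern did not take fructose bisphosphate aldolase (contig 6580) and glyceraldehyde 3-phosphate (contig 2699), chosen after their values were seen, which rose 5.78-fold and 5.59-fold (limma adjusted p = 0.0166 and 0.0409). Muscle structure (55 tested) had a sarcoplasmic calcium-binding protein (contig 6837) at -0.67 and troponin C (contig 5349) at -0.61. Oxidative phosphorylation (45 tested) had a Rieske iron-sulfur polypeptide (contig 620) at 0.37 and NADH dehydrogenase (contig 3717) at -0.61. Cuticle and chitin (76 tested) had a cuticular protein (contig 2980) at -0.84 and an RR-1 family protein (contig 4041) at -0.69. Reproduction and germ line (16 tested), a list of markers of sex and other cell types, had an early meiotic induction protein (contig 6920) at -0.72 and an ovary C/EBPG factor (contig 6942) at -0.23. Photosynthetic and microbial material (5 tested), a list of gut content markers, had bacterial-type proteins (contigs 1712 and 2927) at -0.33 and 0.41. Ribosomal protein L22 (contig 481) was at 0.53. Camera called none of these 9 lists with either correlation. The fits without 1 sample used the preset correlation of 0.01 only, where it was estimated over all samples at 0.323 for oxygen transport and 0.0431 for innate immunity. Without control 2 camera called oxygen transport lower (adjusted p = 0.0372, range 0.0372 to 0.732 over all alternatives). Without control 1 or cyfluthrin 4 it called innate immunity lower (camera adjusted p = 0.0425 and 0.0356, range 0.0356 to 0.732). With cyfluthrin 1 and 2 left out, the samples with the highest cuticle means, which lowers the mean of their group by itself, it called cuticle and chitin lower at a mean of -0.54 (adjusted p = 0.000265) and muscle structure lower at -0.15 (adjusted p = 0.0227), and on row 2 arrays alone or with row as a covariate it called cuticle and chitin lower at -0.84 (adjusted p = 0.000109 and 0.000632). These fits were chosen after seeing the data and used the preset correlation only, where it was estimated at 0.261 for cuticle and 0.167 for muscle. Row 2 holds neither cyfluthrin 1 nor 2. The fits on row 2 arrays and with row as a covariate make the same comparison, cyfluthrin 4 and 8 against the controls. Over all alternatives the adjusted p ranged from 0.000109 to 0.879 for cuticle and from 0.0227 to 0.825 for muscle.

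Within a group, cuticle and chitin transcripts varied most among the 16 lists, with a median SD of 0.826 against 0.365 over all tested probes. The mean of the cuticle probes ran from -2.74 (control 5) to -1.48 (control 2) in controls and from -2.88 (cyfluthrin 8) to -0.81 (cyfluthrin 1) in cyfluthrin samples. Cyfluthrin 1 and 2 also stood apart on the first principal component, which held 36.5% of the variance. Of the 100 probes with the largest loadings on it, 8 were cuticle probes, against 76 of 7721 tested. That was more than this share gives (Fisher's exact test, p = 5.45e-06, across probes, which are not independent). The second component also held 8 (Fisher's exact test, p = 5.45e-06), and there cyfluthrin 1 and 2 lay on opposite sides (-40.1 and 26.0). Probes were not scaled, so a list with a large SD tends to reach large loadings. Over all tested probes the median SD was 0.350 in controls and 0.350 in cyfluthrin samples (exact permutation test over 792 splits, two-sided p = 0.989).

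**Figure D3:**
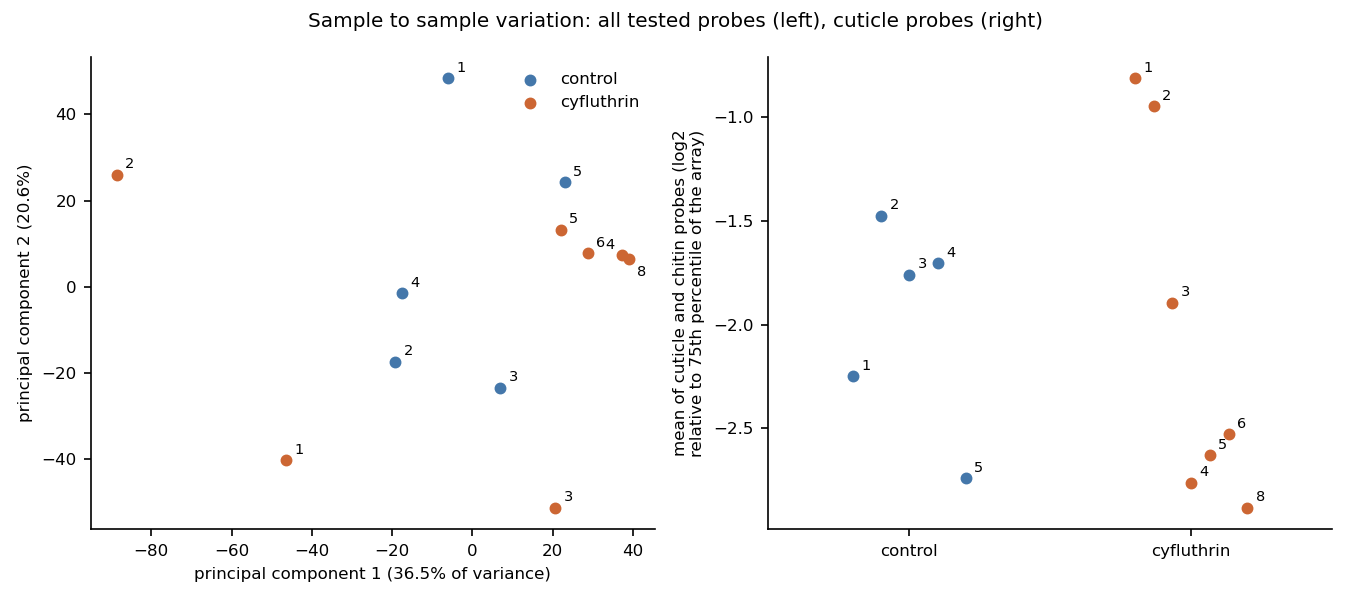
Left, the first and second principal components of the 7721 tested probes (percent of variance on the axes), 1 point per sample, numbered by sample; right, the mean log2 signal of the 76 cuticle and chitin probes in each sample. Cyfluthrin 1 and 2 lie at the left of the first component and have the highest cuticle means, -0.81 and -0.95.

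Repeat arrays of the same sample agreed far more closely than arrays of different samples. Over the 6132 probes well above background on every array, the log2 values of the repeat pairs correlated at 0.997 and 0.996 across probes, with an SD of the difference of 0.176 and 0.205. Arrays of different control samples differed with a median SD of 0.734 and those of different cyfluthrin samples with 0.802. Cyfluthrin 4 and 8, which the labels give as different samples, came closest to a repeat pair, with an SD of 0.295 and 0.305. No measure of array quality differed between the groups after adjustment. Controls had 85.1% ± 6.23 of probes well above background and cyfluthrin samples 89.7% ± 2.28 (SD, n = 5 and 7, exact permutation test, two-sided, p = 0.0518, adjusted over 6 measures 0.155), and the 75th percentile of signal was 426 ± 95.2 against 585 ± 136 (exact permutation p = 0.0518, adjusted 0.155). Without cyfluthrin 2 the lowest adjusted p among these measures was 0.039 (exact permutation test).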

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

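In each group of 5 or 7 samples, the highest and lowest sample was compared with its nearest neighbour for array measures, named probes and list means. Of 138 groups compared 9 held a sample whose gap to the others was a large part of the range, where chance gives about 6.9, 1 in 20.

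Of 4 tested probes named hemocyanin subunit 1 and 2 with the haemocyanin name of contig 356, only 1 each was examined here. Both stood out. They encode the oxygen carrier of crustacean blood and were far lower in control 2 than in the other controls. Contig 356 was at -1.24 in control 2 against 2.01 to 2.70 in the other controls, and hemocyanin subunit 1 (contig 807) at -0.57 against 2.31 to 3.28. Heat shock protein 70 (contig 2087) was at 0.28 in cyfluthrin 5, where the other cyfluthrin samples lay between -2.11 and -1.18. Troponin C (contig 5349) was at -1.34 in cyfluthrin 1, below -0.55 to 0.01 in the others. The 26S proteasome subunit 6 probe (contig 2839) was at -5.93 in cyfluthrin 4, below -5.28 to -4.83. The mean of the muscle list was -0.75 in cyfluthrin 2, above -1.28 to -1.09. Control 5 had 74.3% of probes well above background against 85.7% to 89.5% in the other controls. Median background intensity was 56 in control 5 against 51 to 52, and 57 in cyfluthrin 6 against 50.5 to 52, and these are the only samples on slide 4.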

How the results depend on the processing

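The fits with row 2 arrays, without cyfluthrin 1 and 2, with a cuticle component, with cyfluthrin 4 and 8 averaged, and the list tests without the 16 strongest probes, with slide as a block or with row were chosen after seeing the data. Against 47 probes, limma called 19 with normexp, 89 with the 14 arrays as separate samples, 84 with slide as a random block, 3 with row as a covariate and 12 on row 2 arrays alone, of which 4 were among the 47. Where tested, all 47 kept their direction, as the 41 whose groups do not overlap must in any subset of the samples. Leaving out 1 sample gave 21 to 45 probes. Row 1 holds cyfluthrin samples only, so the fit with row as a covariate also sets only cyfluthrin 4 and 8 against the controls. Repeat arrays taken as separate samples are not independent, and the fit with slide as a random block also took them so. Otherwise the cause was not tested. The remaining 15 settings gave 32 to 66 probes. Deviations of same-numbered samples correlated at -0.37 to 0.57 (mean 0.13) and only control 3 matched its own number best, so there is little sign of pairing. With the replicate block by sample number limma called 0 probes (526 at an unadjusted p under 0.05), although the median log2 fold change of the 16 strongest was 2.86, and with the title number on 14 arrays 22. In the fit by sample number cyfluthrin 6 and 8 have no control of their number, so they add nothing to the fold changes.

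Against 1 list called by camera, 0 were called with an estimated correlation, with quantile normalisation, with the replicate block, with probes of the same name averaged or with slide as a block, and 3 without cyfluthrin 1 and 2. Row 2 arrays alone and row as a covariate, which make the same comparison, also gave 1, which was cuticle and not digestive enzymes. Leaving out 1 sample gave 0 to 2. The cause was not tested. Measures of array quality past the threshold went from 0 to between 0 and 1 when samples were left out, and the difference in spread stayed within -0.03 to 0.05, and was 0.36 with normexp (exact permutation p = 0.298). Of the 19 named probes called, 10 kept their call when any 1 sample was left out, and 9 lost it with normexp. One uncalled value changed sign, the ovary C/EBPG factor with normexp, at 0.0785 (cause not tested). For the 4 called probes below background on every control array, signal allows only a lower bound of the fold change.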

Other observations

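The tests of covariation among the 16 probes, of row 2 arrays and of the other heat shock names were chosen after the results were seen. Of 100 splits of the 12 samples into 5 and 7 drawn at random, 2 gave as many probes as the real 47, the real split included. This is a share under 0.05. The comparison takes the samples as interchangeable, which the layout of rows goes against and the labels leave open. Chance is therefore not excluded. The highest other split gave 160 probes and 97 gave none. That split set control 2 and 3 and cyfluthrin 1, 2 and 3 against the rest, with cuticle means of -1.90 to -0.81 against -2.88 to -1.70, which points to a structure of the samples other than exposure.

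The 16 probes at least 4-fold higher in cyfluthrin varied together from sample to sample. Their mean ran from -2.70 to -0.97 in controls and from -0.18 to 2.08 in cyfluthrin samples. Besides the 60S ribosomal protein, heat shock protein 90 and actin they include fructose bisphosphate aldolase (contig 6580, log2 fold change 2.53) and glyceraldehyde 3-phosphate (contig 2699, 2.48), both described by glycolytic names and chosen after their values were seen. A further 9 probes followed their mean at a residual correlation over 0.9, and 6 of these were at least 4-fold higher without passing, among them a cysteine protease (contig 7908, 2.65 ± 0.55, limma adjusted p = 0.0549). Another of the 9, a cytoplasmic threonyl-tRNA probe (contig 938), was at 0.08 ± 0.19 (limma adjusted p = 0.977) in spite of a residual correlation of 0.925.

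A hypothesis for the 16 probes is transcripts of another organism living in or on the animals, such as an alveolate protist, since ALVEOLIN3 (contig 4088), described from a dinoflagellate and 3.92-fold higher, correlated with their mean after removing group means (0.89). The median pairwise residual correlation of the 16 was 0.910, against 0.08 among the other 14 called rises, and their median probe GC content was 40%, outside the 44.2% to 50% of random sets of 16 drawn from the 3179 tested probes with a name, to which 14 of the 16 belong. The tables argue against the slide (median log2 fold change 2.78 with slide as a block). On row 2 arrays the median was 1.86, from cyfluthrin 4 and 8 only. These differed by an SD of 0.295 and 0.305 and may not be independent. The 16 were chosen on these same samples, and all controls lie in row 2, so a rise there was largely set by the choice. Cyfluthrin 4 and 8 also had the lowest means of the 16 in their group (-0.18 and 0.04), so row stays open. ALVEOLIN3 is itself not among the 16, and contig 6094, which is, was described from a plant (*Vitis vinifera*). Of the other 8 tested probes with alveolate names limma called 0 (1 at an unadjusted p under 0.05), with residual correlations with the 16 from -0.46 to 0.61. Contig 938 varied with the 16 at a log2 fold change of 0.08, so such a correlation need not come with a rise. The other probes outside the 16 with a residual correlation over 0.9 were at 1.29 to 3.09. A shared regulator within the amphipod, an effect of exposure on the animals or on such an organism, and a heat shock response stay open, the last because the other 13 probes named heat shock protein 70 or 90 (median -0.12 ± 1.51, SD) went both ways and are those left after the strongest rises were set aside.

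The 5 heat shock probes that fell had a median log2 fold change of -2.04. The tables argue against slide (-2.03 with slide as a block). On row 2 arrays the median was -1.90, the highest at -1.49, on cyfluthrin 4 and 8 only, whose closeness leaves their independence in doubt. The probes were chosen on these same samples, so this does not decide on row. The median pairwise residual correlation of 0.363 (from -0.12 to 0.89) argues against a single transcript behind all 5, which differ in name. It cannot tell whether the heat shock protein 70 probes (contigs 2087, 2561 and 2088) share a transcript. All of these lay highest of their group in cyfluthrin 5 (0.28, 1.73 and -1.02). An effect of exposure on chaperone transcripts may remain as a hypothesis, which was found and examined on the same samples, and the share that row adds stays open.

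Cuticle probes varied most between samples of the same group. The first component of the list did not follow the share of probes well above background (Pearson's r = 0.120, permutation p = 0.781; Spearman's rho = -0.0979, permutation p = 0.766; r = -0.48 without the 2 samples farthest from the median; a single relation computed). Repeat arrays on slides 1 and 3, the only slides with such arrays, differed in these probes by 0.122 of the SD between different samples of a group, and on slide 3 the list mean was -0.81 in cyfluthrin 1 and -2.63 in cyfluthrin 5, which argues against these slides as the cause and leaves slides 2 and 4 open. Samples taken at different stages of the moult cycle could give this spread, but stage was not recorded in the labels and no biological explanation was tested.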
